A study of Oryzias latipes and Danio rerio with 6 samples.

How the data were processed

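The data were made by iDamID-seq, a method in which the bacterial adenine methylase Dam is fused to a protein of interest and marks GATC sites near the places where that protein touches DNA. Per the labels' protocols, mRNA for each fusion was injected into wild-type embryos, genomic DNA was taken from whole embryos, unmethylated sites were digested with DpnII and methylated sites were cleaved with DpnI. Adapters were then ligated, and the fragments were amplified by 25 cycles of PCR and sequenced on an Illumina instrument. The 6 samples comprised 3 from medaka (Dam fused to Yap1, Yap1b or GFP) and 3 from zebrafish (Dam fused to Yap1, Taz or GFP), with 1 sample per group. The sample labels gave stage 16 for medaka and 80% epiboly for zebrafish, whereas the protocol text gave 80% epiboly for both species, so the medaka stage is stated here as the sample labels give it. Per the labels' protocols, 40 embryos entered each replicate and 3 replicates were used for each sample. Each sample was represented by region lists without values per replicate, so no spread between replicates could be computed.

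The deposited files were 8 region lists, 1 positive and 1 control list for each of the 4 factor fusions. The control lists were deposited under the Dam-GFP sample of the species, and the factor that each was paired with was read from the name of the list. Per the submitters' processing notes, cutadapt, Bowtie2, SAMtools and bedtools were used, without versions, and the build named was GRCz10 (danRer10), a zebrafish assembly. The medaka build, the region caller and its thresholds were not given in the sources used here. The fifth column of each list held a score made by the authors, a whole number whose quantity was not stated. The positive and the control list of a factor shared the same lowest deposited score, and the highest score over the pair was 1000 in each of the 4 pairs. The score was used only to rank and filter regions within a list. Read counts and sequencing depth were not given in the lists used here, so the depth behind each region was unknown, and the intervals below cover counting of regions only.

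A pair of regions was called shared when it overlapped by at least 1 bp. Overlap was compared with 10000 circular shifts of 1 list along each sequence, which keep region lengths and clustering, in a one-sided permutation test whose smallest possible p was 0.0001. The length of each sequence was taken as the last region end over the 4 lists of the species, which is a lower bound of its true length. The comparison between species used a two-sided Fisher's exact test on regions of the shorter list of each species, shared or not shared. Shares carry Wilson 95% intervals, odds ratios carry 95% intervals from the log odds, and regions are not independent replicates. Because both comparisons of a species used the same Dam-GFP control, the overlap of both control lists and the crossed overlaps of a positive with a control list were computed beside each positive overlap. Unchanged groups could not be simulated against the control, and the control could not be split, since neither can be done without read counts.

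These tests, the alternatives for them and the rule for naming regions were fixed before the data were examined. The rule took, where no annotation of the build was used, the 5 regions of highest score in each positive list, and per species the 5 longest shared regions and the 5 longest regions found in 1 list only. The following were chosen after the data had been seen: sharing in positive against control lists, sharing by score class, and sharing per chromosome. The distribution over chromosomes, unplaced sequences and chromosome ends, the clustering of regions and the count of short regions were also chosen then. Score and sharing were compared by the difference of median scores with 100000 label permutations, two-sided, with Benjamini-Hochberg adjustment over 8 lists. Chromosome shares were compared by two-sided Fisher's exact tests, adjusted within each list pair over the chromosomes and the unplaced sequences. A chromosome end was the first or last 1 Mb of an assembled chromosome, and positive and control shares were also compared per chromosome by 100000 random sign flips, adjusted over 4 list pairs. Clusters were regions separated by at most 10 kb. Alternatives added after the data had been seen merged regions within 10 or 50 kb, kept the top-scored part of each list, left out the chromosome ends or widened them to 2 Mb. What merging alone does at chromosome ends was computed from 100 simulated placements, in which the regions of each zebrafish end were spread at random over that end.

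The overlap test was tested on simulated data built from the medaka Yap1 comparison, with 4212 regions and 1000 shifts per case. Regions of both lists were placed evenly at random along their sequences before planting. The clustering of the deposited lists was thereby lost, so these cases do not test the shifts on clustered regions. With 0 planted regions the excess over the shifts was 10.4 regions (permutation p = 0.117). With 210 planted regions the excess was 210.1, and with 1263 planted regions it was 1215, each at permutation p = 0.000999, the smallest these shifts allow. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. No gene annotation or genome sequence of either build was used here, so distances to transcription starts, TEAD motif density, target genes, genes shared between species and the 12 gene lists fixed beforehand were not analysed here. Coordinates are those of the deposited lists, with starts converted to 1-based counting.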

Results

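The deposited data mapped where the Hippo pathway co-activators Yap1, Yap1b and Taz contacted DNA in whole fish embryos. These proteins carry no DNA-binding domain of their own and reach chromatin through partners, chiefly TEAD factors. Yap1b is described by the study as an additional Yap family member of teleost fish. In medaka, Dam-Yap1 and Dam-Yap1b were each set against Dam-GFP at stage 16. In zebrafish, Dam-Yap1 and Dam-Taz were each set against Dam-GFP at 80% epiboly. Each factor had a positive list, and a control list deposited under Dam-GFP. Every group was 1 sample, so differences between lists have no replicate check and p-values on regions cover counting only.

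The medaka positive lists held 4212 regions for Yap1 and 3792 for Yap1b, and the paired control lists held 5190 and 3794. The zebrafish positive lists held 7553 regions for Yap1 and 8608 for Taz, and the control lists held 8538 and 11025. Positive regions had median lengths of 944.5 bp (medaka Yap1), 949 bp (Yap1b), 957 bp (zebrafish Yap1) and 982 bp (Taz). Control regions were shorter at the median, at 830, 812, 907.5 and 804 bp in the same order. Regions under 300 bp made up 6.41%, 5.72%, 5.27% and 7.53% of the positive lists and 0.231%, 0.264%, 0.433% and 0.871% of the control lists. The positive regions covered 4642 kb for medaka Yap1, 4176 kb for Yap1b, 8896 kb for zebrafish Yap1 and 10660 kb for Taz. The authors' scores reached 1000 in each positive list and at most 331, 401, 328 and 414 in the control lists. Read depth was unknown.

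The first comparison asked how far the medaka paralogues Yap1 and Yap1b occupied the same regions. Most Yap1b regions were also Yap1 regions: 2438 of 3792 Yap1b positive regions (64.3%, Wilson 95% interval 62.8 to 65.8) overlapped a Yap1 positive region. From the other side, 2452 of 4212 Yap1 regions (58.2%, 56.7 to 59.7) overlapped a Yap1b region. Exactly the same start and end were listed for 1483 regions, 60.8% of the shared Yap1b regions. In the control lists this held for 1192 regions, 76.1% of the shared Yap1b control regions, so equal edges were not particular to the positive lists. Circular shifts gave a mean overlap of 3.66% for the Yap1b list, a 17.6-fold difference, and 3.33% for the Yap1 list, a 17.5-fold difference (one-sided permutation p = 0.0001 for each, the smallest 10000 shifts can give). On assembled chromosomes alone, where no short scaffold limits the shifts, 63.9% of Yap1b regions were shared, 59.1-fold over the shifts.

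The Dam-GFP control lists were compared in the same way. The Yap1b control list shared 41.3% (39.7 to 42.9) of its regions with the Yap1 control list, 10.8-fold over the shifts. The Yap1 control list shared 30.3% (29.1 to 31.6). Crossed overlaps were rare: 2 of 3792 Yap1b positive regions met a Yap1 control region, against 49.6 in the mean shift, and 3 of 4212 Yap1 positive regions met a Yap1b control region, against 43.6 (one-sided permutation p for a deficit = 0.0001 for each). The odds of sharing were higher in the positive than in the control list, by 2.56 (2.33 to 2.81) for Yap1b and 3.20 (2.94 to 3.49) for Yap1 (Fisher's exact test, p = 3.20e-90 and 7.22e-164). Both factors used the same Dam-GFP control, so part of the overlap, and of the deficit in the crossed overlaps, may come from that control.

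Medaka regions of high score were the ones most often shared. In the Yap1 positive list the shared share went from 37.4% in the lowest of 4 equal score classes through 51.9% and 61.7% to 81.9% in the highest. The Yap1b list went from 42.9% through 56.8% and 70.6% to 86.9%. Median scores were 143 for shared and 105 for unshared Yap1 regions, and 191 and 141 for Yap1b (permutation p = 1e-05 for each, the smallest 100000 permutations can give; adjusted p = 1.33e-05). Of the 100 top-scored Yap1 regions 91 lay in the Yap1b list, and of the 100 top-scored Yap1b regions 97 lay in the Yap1 list. Only 31 were in the top 100 of both. In the control lists the shared share went from 27.9% to 33.4% (Yap1) and from 26.8% to 52.3% (Yap1b) between the lowest and the highest class.

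All 5 top-scored medaka Yap1 regions were Yap1b regions as well. They lay on scaffold2494 (1805 to 3324, score 1000), chromosome 17 (29603087 to 29603599, score 935), chromosome 19 (19640717 to 19642317, score 934), chromosome 24 (11743802 to 11746424, score 903) and ultracontig182 (3358916 to 3359419, score 805). The 5 top-scored Yap1b regions were all Yap1 regions. They lay on chromosome 21 (6823779 to 6824833, score 1000), chromosome 4 (23730220 to 23731120, score 989), ultracontig182 (2555167 to 2556438, score 942), chromosome 1 (1877568 to 1878905, score 938) and chromosome 15 (12091785 to 12094485, score 887). The longest shared region spanned 8286 bp of chromosome 20 (13034135 to 13042420), followed by 5895 bp on scaffold1323 (29773 to 35667), 5682 bp of chromosome 16 (24537783 to 24543464), 5504 bp of chromosome 7 (21842712 to 21848215) and 5082 bp on scaffold1623 (331 to 5412). Among the 5 longest regions of 1 list only, 4 belonged to Yap1, on chromosome 11 (689247 to 694683), chromosome 16 (24650645 to 24656008), chromosome 4 (15582589 to 15587147) and chromosome 24 (6746327 to 6750843). The remaining region belonged to Yap1b, on chromosome 15 (20926656 to 20931501). The medaka build is not given in the sources used here, so these positions were not tied to genes.

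**Figure D1:**
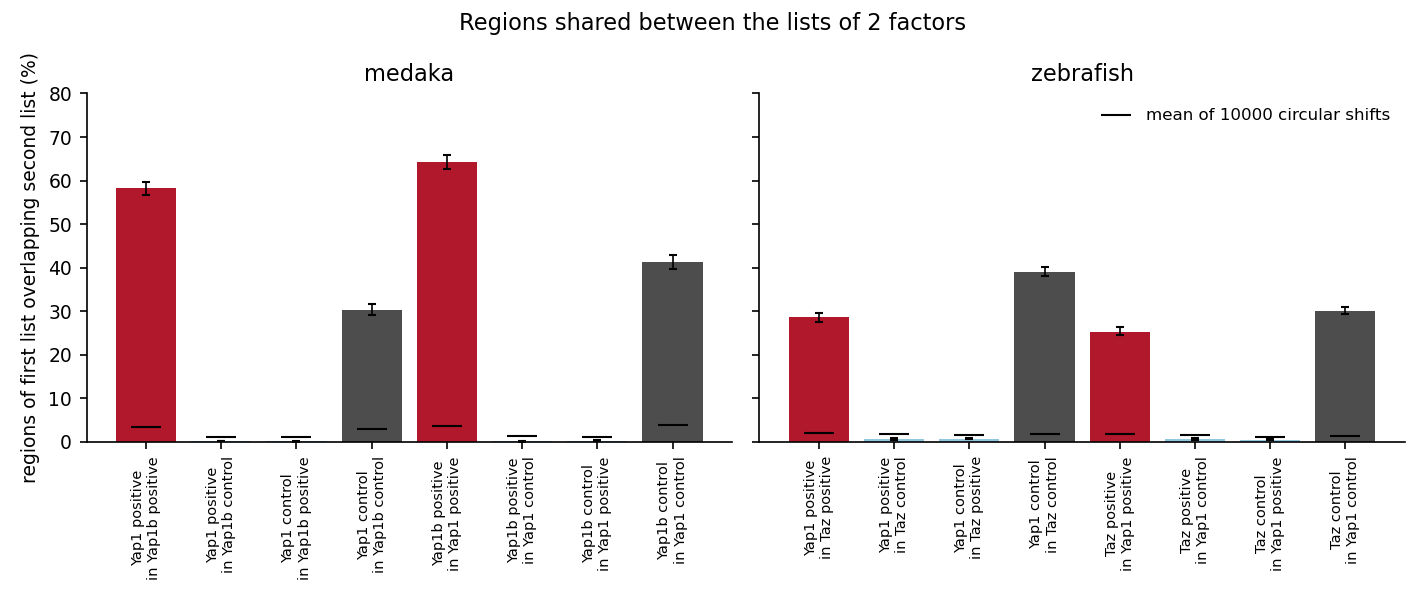
Share of regions of the first list that overlap the second list by at least 1 bp (%), for each ordered pair of lists of different factors in medaka and zebrafish. Red bars are positive lists, grey bars control lists and blue bars crossed pairs; error bars are Wilson 95% intervals and black dashes the mean of 10000 circular shifts, and the medaka positive lists share 58.2% and 64.3% against 28.6% and 25.3% in zebrafish.

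The second comparison set zebrafish Yap1 against Taz, the other vertebrate member of the family. A minority of each list was common to both: 2159 of 7553 Yap1 positive regions (28.6%, 27.6 to 29.6) overlapped a Taz positive region, and 2178 of 8608 Taz regions (25.3%, 24.4 to 26.2) overlapped a Yap1 region. Identical edges were listed for 948 regions, 43.9% of the shared Yap1 regions, against 2402 in the control lists, 72.1% of the shared Yap1 control regions. The shifts gave 1.93% and 1.74%, differences of 14.8-fold and 14.6-fold (one-sided permutation p = 0.0001 for each, the smallest possible). Most regions of each factor, 5394 for Yap1 and 6430 for Taz, had no counterpart in the other list.

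In zebrafish the Dam-GFP control lists shared more than the positive lists did. The Yap1 control list shared 39.0% (38.0 to 40.1) of its regions with the Taz control list, 21.3-fold over the shifts, and the Taz control list shared 30.1% (29.3 to 31.0). The odds of sharing, positive over control, were 0.625 (0.585 to 0.668) for Yap1 and 0.786 (0.738 to 0.837) for Taz (Fisher's exact test, p = 1.68e-44 and 8.23e-14). Crossed overlaps covered 0.596% of Yap1 positive regions, against 1.72% in the shifts, and 54 of 8608 Taz positive regions, against 128.7 (one-sided permutation p for a deficit = 0.0001 for each). As in medaka, part of the positive overlap and of the crossed deficit may come from the common Dam-GFP control.

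Zebrafish Yap1 regions were shared most often in the highest score class, at 51.6% (49.3 to 53.8), against 19.3%, 23.4% and 20.1% in the lower classes. The Taz list went from 19.6% in the lowest class to 33.8% in the highest. In the Yap1 control list the share went from 39.9% in the lowest class through 43.2% and 43.5% to 29.6% in the highest. The Taz control list went from 15.6% through 32.1% and 39.1% to 33.7%. Median scores of shared and unshared regions were 117 and 89 for Yap1 and 119 and 103 for Taz (permutation p = 1e-05 for each, the smallest possible; adjusted p = 1.33e-05). Of the 100 top-scored regions, 66 of Yap1 and 40 of Taz lay in the other factor's positive list, while 6 were in the top 100 of both.

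Of the 5 top-scored zebrafish Yap1 regions (GRCz10), 3 were also Taz regions, on chromosome 10 (13596329 to 13599115, score 967), chromosome 11 (3841938 to 3842851, score 850) and chromosome 18 (17869055 to 17872500, score 829). In the Taz list their scores were 125, 130 and 329. The Yap1 regions on chromosome 23 (13990412 to 13991970, score 1000) and chromosome 16 (32793993 to 32797527, score 830) were not in the Taz list. Of the 5 top-scored Taz regions, those on chromosome 23 (18412969 to 18413739, score 1000), chromosome 5 (355911 to 357025, score 715) and chromosome 21 (41292661 to 41293893, score 713) were Yap1 regions too. In the Yap1 list their scores were 57, 68 and 617, of which 57 was the lowest score of that list. The Taz regions on chromosome 16 (50730630 to 50732913, score 996) and chromosome 4 (36077131 to 36077987, score 778) were not. Among the 5 longest shared regions, 3 lay on chromosome 4 (37812426 to 37822371, 37269499 to 37275937 and 42613081 to 42619313), with the others on chromosome 20 (152855 to 161325) and chromosome 14 (31058869 to 31066495). Yap1 alone had a region of 16598 bp on chromosome 17 (23347026 to 23363623) and further regions of 12683 and 11225 bp on chromosome 4 (65279693 to 65292375 and 59571985 to 59583209). Taz alone had regions of 10374 bp on chromosome 16 (54595347 to 54605720) and 9499 bp on the unplaced sequence chrUn_KN150170v1 (38214 to 47712).

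**Figure D2:**
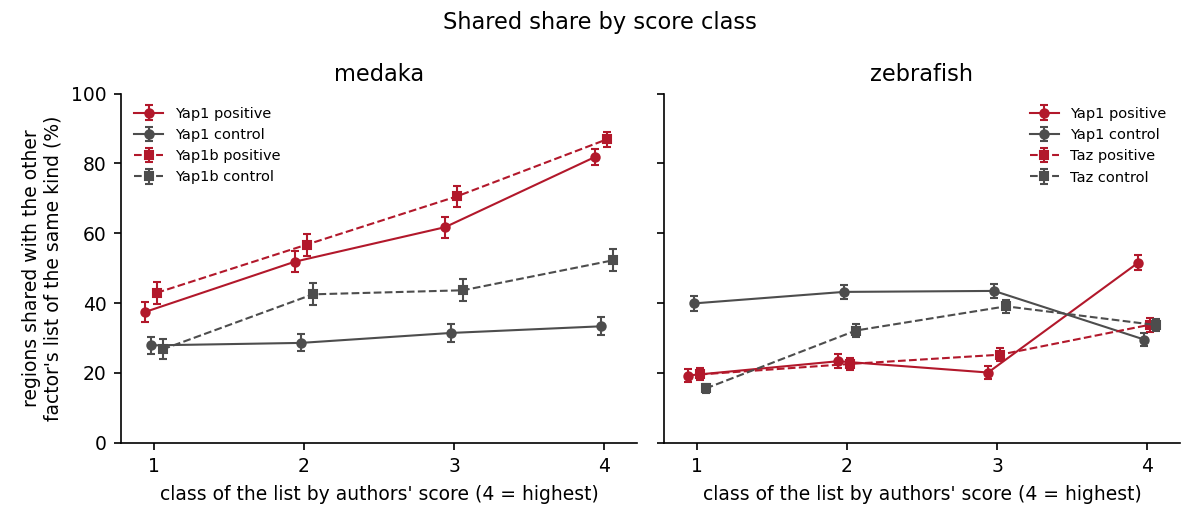
Share of regions that overlap the other factor's list of the same kind (%), by class of each list by the authors' score, from 1 (lowest) to 4 (highest), with Wilson 95% intervals. Red is positive and grey control, circles are Yap1 and squares Yap1b or Taz; the medaka Yap1b positive list goes from 42.9% to 86.9% and the zebrafish Yap1 positive list has 51.6% in the highest class.

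The third comparison set the medaka pair against the zebrafish pair. The medaka Yap1 and Yap1b lists shared a larger part of their positive regions than the zebrafish Yap1 and Taz lists, 64.3% against 28.6% of the shorter list, an odds ratio of 4.50 (4.14 to 4.89; Fisher's exact test, two-sided, p = 3.22e-292). The control lists of the species differed by 2.26 percentage points, 41.3% against 39.0%, with a 95% interval of the odds ratio from 1.02 to 1.19 (Fisher's exact test, p = 0.0186; p = 0.797 with the longer lists as denominators). The odds ratio of the positive lists was 4.09 times that of the control lists (3.65 to 4.59). Species and partner protein changed together between the pairs, so the comparison does not separate them.

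Sharing was also compared chromosome by chromosome. In medaka the shared share of Yap1b positive regions averaged 63.7% ± 5.33 (SD over 24 chromosomes) and lay above that of the control list on 24 of 24 chromosomes, where the control mean was 40.4% ± 3.16. In zebrafish the shared share of Yap1 positive regions averaged 27.2% ± 4.75 (SD over 25 chromosomes) and lay below that of the control list on 24 of 25, where the control mean was 39.6% ± 3.99 (permutation p = 1e-05 by sign flips in each species, the smallest possible). The exception was zebrafish chromosome 4, where 45.6% of 638 Yap1 positive regions were shared, against 26.1% of 414 control regions. Between species the chromosome means differed by 36.5 percentage points for positive lists (permutation p = 1e-05) and by 0.809 for control lists (permutation p = 0.448). Chromosomes of the same sample are not replicates, so p-values over chromosomes, here and below, do not cover differences between samples.

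Where the regions lay was then compared between positive and Dam-GFP control lists, and the zebrafish Taz regions were concentrated at chromosome ends. Of the 8128 Taz positive regions on assembled chromosomes, 2071 (25.5%, 24.5 to 26.4) lay within 1 Mb of an end, against 454 of 10822 Taz control regions (4.20%, 3.83 to 4.59). These ends make up 3.73% of the assembled length. The zebrafish Yap1 list had 7.77% (7.18 to 8.40) of its positive and 4.73% (4.30 to 5.21) of its control regions there. In medaka the contrast with the control lists had the opposite direction: 7.38% of Yap1 and 6.44% of Yap1b positive regions lay at chromosome ends, against 13.1% and 14.1% of the control regions, with the ends making up 6.64% of the assembled length. The medaka positive shares were thus near the share of length, and the control shares lay above it.

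The odds ratio for chromosome ends, positive over control, was 7.81 (7.02 to 8.69) for Taz, 1.70 (1.49 to 1.94) for zebrafish Yap1, 0.530 (0.454 to 0.620) for medaka Yap1 and 0.421 (0.353 to 0.502) for Yap1b. Per chromosome, the Taz positive share was the higher on 25 of 25 chromosomes, by a mean of 22.2 ± 7.80 percentage points (SD). The Yap1 share was the higher on 20 of 25 zebrafish chromosomes, and the medaka positive shares were the lower on 24 of 24 chromosomes for each factor (permutation by sign flips, adjusted p = 5e-05 for zebrafish Yap1 and 1.33e-05 for each of the others). Merging regions within 10 kb gave 4.78 for Taz, 1.48 for zebrafish Yap1, 0.566 for medaka Yap1 and 0.435 for Yap1b. Merging within 50 kb gave 1.73, 1.22, 0.825 and 0.584 in the same order, of which medaka Yap1 did not pass (Fisher's exact test, p = 0.0606). At these ends 299 of 2071 Taz regions (14.4%) overlapped a Yap1 region, against 29.4% of Taz regions elsewhere on assembled chromosomes. From the other side, 283 of 569 Yap1 regions (49.7%) overlapped a Taz region, against 26.3% elsewhere. Both counts at the ends are the same overlaps counted over lists of different size.

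**Figure D3:**
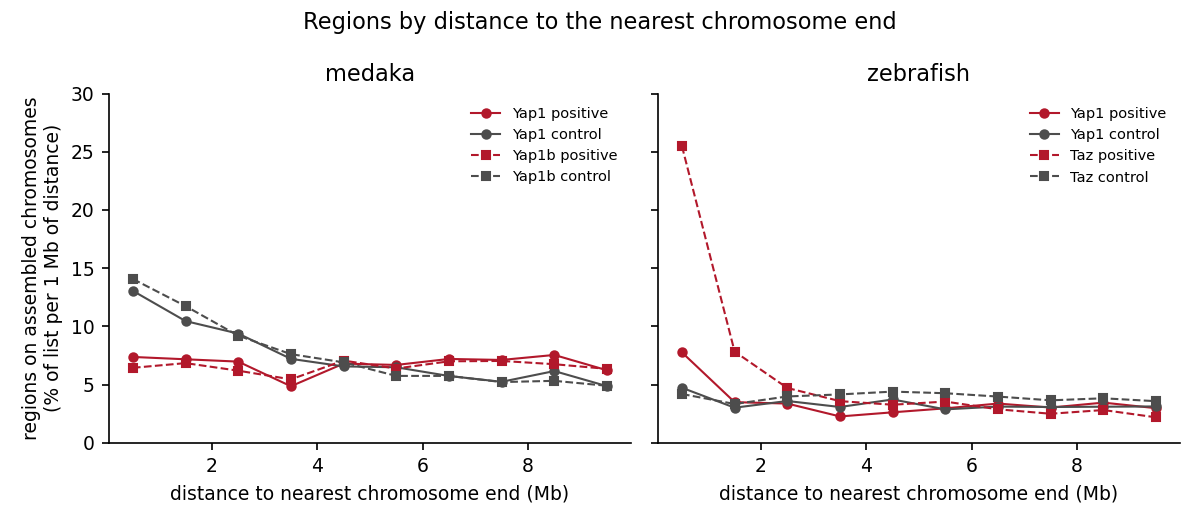
Regions on assembled chromosomes by distance to the nearest chromosome end, as the percentage of each list per 1 Mb of distance, with red for positive and grey for control lists, circles for Yap1 and squares for Yap1b or Taz. The zebrafish Taz positive list has 25.5% of its regions in the first 1 Mb and 7.84% in the next, while the other zebrafish lists lie between 4.20% and 7.77% in the first.

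Zebrafish chromosome 4 held more positive than control regions for both factors. It carried 8.45% (7.84 to 9.10) of Yap1 positive and 4.85% (4.41 to 5.33) of Yap1 control regions, an odds ratio of 1.81 (1.59 to 2.06, adjusted p = 1.00e-18, Fisher's exact test). For Taz it carried 8.02% (7.46 to 8.61) and 4.28% (3.92 to 4.68), an odds ratio of 1.95 (1.73 to 2.20, adjusted p = 1.03e-26, Fisher's exact test). The chromosome, whose long arm is known to be rich in repeated sequence, made up 5.72% of the assembled length. In 4 equal parts of the chromosome from its start, the Yap1 odds ratios were 2.62 (1.95 to 3.52), 1.04 (0.803 to 1.35), 1.97 (1.54 to 2.52) and 2.02 (1.61 to 2.52). The Taz odds ratios were 0.803 (0.625 to 1.03), 1.61 (1.24 to 2.09), 3.89 (2.96 to 5.10) and 2.63 (2.13 to 3.26).

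**Figure D4:**
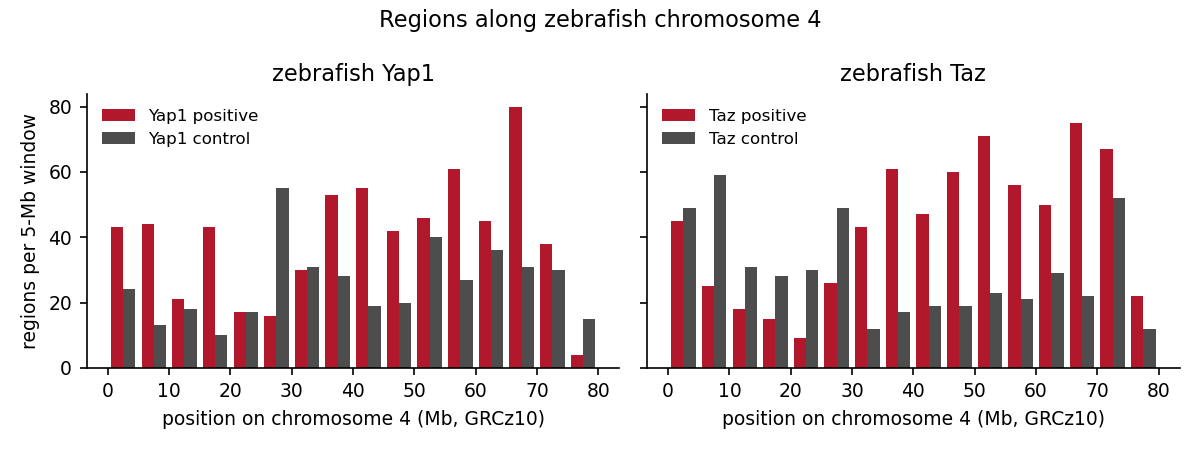
Number of regions in 5-Mb windows along zebrafish chromosome 4 (GRCz10), for Yap1 and for Taz, with positive regions in red and control regions in grey. Yap1 positive regions reach 80 in the window from 65 to 70 Mb, against 31 control regions, and Taz reaches 75 there, against 22.

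Medaka chromosomes also differed between positive and control lists. Chromosome 2 held 1.33% of Yap1 and 1.42% of Yap1b positive regions, against 3.03% and 2.77% of the control regions, odds ratios of 0.432 (0.318 to 0.588) and 0.508 (0.364 to 0.707). Chromosome 18 was lower in both factors too, at odds ratios of 0.668 and 0.654. Chromosome 20 was higher in both, at 1.61 (1.27 to 2.06) for Yap1 and 1.73 (1.32 to 2.27) for Yap1b, as were chromosome 6 (1.41 and 1.42) and chromosome 7 (1.38 and 1.59). All 10 of these values passed an adjusted p of 0.05 by Fisher's exact test. Shares were taken over all regions of a list, unplaced ones included. The lower unplaced share of the positive lists, given next, raises the odds ratios of the assembled chromosomes together. The tests were not repeated on assembled regions alone, so the higher values of chromosomes 6, 7 and 20 may in part restate that difference. Sequences not placed on a chromosome held 16.9% of Yap1 and 14.8% of Yap1b positive regions, against 22.8% and 25.3% of the control regions, odds ratios of 0.690 (0.622 to 0.765) and 0.516 (0.460 to 0.579). In zebrafish they held more positive than control regions, 5.58% against 1.84% for Taz (odds ratio 3.15, 2.67 to 3.72) and 2.99% against 2.19% for Yap1 (1.38, 1.13 to 1.68), and the Yap1 difference did not pass after merging within 50 kb (1.28) or in the top-scored part of the lists (1.21).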

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

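The odds ratio between species was set before the data were examined, and the tests on the control lists, chromosome ends, merged regions and unplaced sequences were chosen after the data had been seen.

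The medaka pair shared positive regions at 4.50 times the odds of the zebrafish pair (4.14 to 4.89), which drew attention because the same contrast differed between the species. Leaving out the last 1 Mb of every chromosome gave an odds ratio of 4.47 (4.10 to 4.87), with Taz instead of Yap1 as the shorter zebrafish list. The Yap1 share behind 4.50 does not count Taz regions that Yap1 lacks, so this change does not test those at chromosome ends as a cause. Counted on Taz, the zebrafish share was 25.3% with the ends and 28.7% without them. The medaka Yap1b share without the ends was 64.3%, so a gap between the species remained on that count. A general lack of reproducibility in the zebrafish lists stays open: the shared shares of the control lists differed by 2.26 percentage points, against 35.7 for the positive lists, but both control lists of a species rest on the same Dam-GFP sample, whose noise they have in common. Differences in sequencing depth or noise of the single Dam-factor samples remain open too. A biological difference, in that Yap1 and Yap1b may be closer in their partners than Yap1 and Taz, or a difference between the species, also remains open and was not tested.

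Zebrafish Taz positive regions were concentrated within 1 Mb of chromosome ends, and the odds ratio over control was 4.60 times that of zebrafish Yap1 (3.88 to 5.46), so the same contrast differed between the factors. A few dense clusters counted many times are argued against as the whole cause by a Taz odds ratio of 4.78 (4.22 to 5.41) after merging within 10 kb. End regions spread at random over each end gave a mean of 5.56 there, with 100 placements from 5.30 to 5.90. The observed value lay below all of them, so merging lowered it more than random spreading would. Merging within 50 kb gave 1.73 and random spreading 1.62, so that its fall follows from the density itself. A low Dam-GFP signal at chromosome ends, common to both factors, also stays open. The ratio of Taz to Yap1 was 3.23 (2.66 to 3.92) after merging within 10 kb, 5.06 in the top-scored part of the lists and 4.06 for the last 2 Mb. The saturated merging within 50 kb gave 1.42 and random spreading 1.17. A low control would raise both factors alike only if both Dam-factor samples had like depth and cut-offs. Neither was known, so the unequal excess does not decide on this cause. Base composition, repeats, copy number and depth were not tested, and with 1 Taz sample the library and the factor are confounded. The concentration may therefore be technical or biological, and either stays a hypothesis.

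Unplaced sequences differed in direction between the species: with the lists of both factors added, the odds ratio of positive over control regions was 2.25 (1.98 to 2.55) in zebrafish and 0.606 (0.561 to 0.655) in medaka, a ratio of 3.70 (3.20 to 4.29). Regions that both lists of a species share were counted once for each factor, so these intervals are too narrow. Taz carried most of the zebrafish value, at 3.15 against 1.38 for Yap1, and zebrafish Yap1 no longer passed its own test after merging within 50 kb (1.28) or in the top-scored part of the lists (1.21). For Yap1 alone, the ratio of zebrafish to medaka had an interval of 1.60 to 2.49, and was 1.66 (1.27 to 2.17) after merging. The lists named 1265 sequences other than assembled chromosomes in medaka and 424 in zebrafish. Unplaced sequence is thus not a like part of both assemblies, and the contrast does not separate species from assembly.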

How the results depend on the processing

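All 15 alternatives that had been set before the data were examined and were run kept the direction and the side of the threshold of their result. The shared share ranged from 52.3% to 66.2% for medaka Yap1b and from 20.3% to 30.7% for zebrafish Yap1, and the odds ratio between species from 4.11 to 5.19. The fold over the shifts moved more, from 12.4 to 59.1 in medaka and from 9.58 to 48.0 in zebrafish, since both the overlap rule and short scaffolds change the shifted overlap. Of the 45 alternatives chosen after seeing the data, 42 kept both. The other 3 kept their direction but no longer passed the threshold. The zebrafish Yap1 odds ratio for unplaced sequences was 1.28 with regions within 50 kb merged (p = 0.0501) and 1.21 in the top-scored part of the lists (p = 0.209, Fisher's exact tests). The medaka Yap1 odds ratio for chromosome ends was 0.825 with regions within 50 kb merged (p = 0.0606, Fisher's exact test). With all regions these odds ratios were 1.38 (unplaced sequences) and 0.530 (chromosome ends), so the values themselves moved toward no difference. These settings also leave fewer regions to test, and the cause was not tested further. Alternatives for regions near transcription starts, TEAD motif density, genes shared by the paralogues, genes shared between species and gene list members were not run, since no annotation or sequence of the builds was used here. No paired analysis was possible because each group had 1 sample. Depth was unknown, so no limit of detection can be given.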

Other observations

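The tests on clusters, mitochondrial regions and the shared control were chosen after the data had been seen.

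Positive regions of zebrafish Taz often lay in clusters: 41.1% (40.0 to 42.1) had a neighbour within 10 kb, against 22.9% (22.1 to 23.7) of Taz control regions, an odds ratio of 2.34 (2.20 to 2.49). Zebrafish Yap1 went the other way, with 33.6% of positive and 37.6% of control regions (0.839, 0.787 to 0.895). In medaka the values were 25.3% against 21.6% for Yap1 (1.23, 1.12 to 1.36) and 23.5% against 16.6% for Yap1b (1.55, 1.38 to 1.74). The Taz clusters with most regions held 17 regions on chromosome 8 (54110370 to 54189958), 15 on chromosome 18 (50868751 to 50930044) and 14 on chromosome 3 (62165217 to 62208874), and the Yap1 positive list held 4, 2 and 3 regions within these spans. All of these Taz clusters lay within 1 Mb of a chromosome end, where Taz regions were concentrated. The clustered share without the ends was not computed, so the Taz clustering was not told apart from that concentration. The zebrafish Yap1 cluster with most regions held 25 on the unplaced sequence chrUn_KN149688v1 (59293 to 117660), where Taz had 1. In medaka, a Yap1 cluster of 9 regions spanned 46.0 kb of chromosome 11 (4521611 to 4567615), with 4 Yap1b regions in it.

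The mitochondrial genome carried 1 positive region each for medaka Yap1 (14676 to 16714, score 294), medaka Yap1b (15207 to 16714, score 158) and zebrafish Yap1 (5363 to 6574, score 293). The Taz list and the 4 control lists had none there.

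Sharing above the shifts in both species may come in part from the Dam-GFP control that both comparisons of a species have in common. Among the top 50% of each list by score, the odds of sharing in the positive over the control lists were 2.93 (2.57 to 3.35) in medaka and 0.721 (0.652 to 0.798) in zebrafish. In the highest of 4 score classes of the zebrafish lists, 51.6% of Yap1 positive regions were shared against 29.6% of Yap1 control regions, and 33.8% against 33.7% for Taz. Control sharing is therefore no level of no effect for positive lists. Sharing from the control and sharing of sites of the factors cannot be told apart in either species without read counts.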
